A study of Mus musculus with 12 samples.

How the data were processed

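RNA was measured in 12 samples of sorted mouse kidney cells taken at postnatal day 0. Per the labels' protocols, Six2-expressing cells carrying a tdTomato reporter were isolated by flow cytometry, cDNA was made with a SMART-Seq kit for low RNA input, and sequencing libraries were made from the cDNA. Groups and replicate numbers were taken from the sample titles, which call each sample control or mutant and high or low expression. The titles do not say which signal was high or low. The word mutant is taken from the titles, and Eed, the Polycomb group member of the series title, is named in no sample label. There were 4 control low, 2 control high, 4 mutant low and 2 mutant high samples. The labels do not say whether samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

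The deposited table holds estimated counts of fragments per transcript, not normalized, with 1 column per sample. The file's own title calls the values raw fragments of CuffDiff2, while the submitters' processing notes name Bowtie2, HTSeq, DESeq2 and the build mm9 without roles or versions. The aligner's settings, the handling of fragments with several alignments and any use of strand are not given in the sources used here. The 55418 rows carry UCSC transcript identifiers and mm9 positions. Of these rows, 303 had no position and held no fragments. Whether start positions count from 0 or 1 is not stated, and they are printed as deposited.

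Between 41.9% and 47.9% of a library's transcript values were whole numbers within 0.01, because fragments were divided between isoforms. Transcripts overlapping on the same strand were therefore summed to 26699 loci, and 99.4% to 99.9% of the sums were whole within the same tolerance. The sums were rounded to whole counts. A locus is named by its most abundant transcript. The planned tests assumed counts per gene, and locus sums took their place. SMART-Seq libraries do not mark strand by default, so reads of overlapping antisense loci cannot be told apart, nor could reads shared between near-identical copies be examined.

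The file does not pair identifiers with gene names, and the reference tables supplied for another build do not hold these identifiers. The gene lists fixed before the data were examined, and the 4 genes Eed, Ezh2, Suz12 and Six2, were therefore not analysed here, so the targeted gene was not used to check the labels. The naming rule, fixed before the data were examined, took for each comparison the 8 loci with the largest rise and the 8 with the largest fall. They needed an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 5 CPM (counts scaled to library size) and CPM ranges that did not overlap. For the difference of mutant effects it took the 5 smallest adjusted p in each direction. Identifiers are printed only for the first 2 loci in each direction of the first comparison, and the others are given as groups or by position. One locus, on chromosome 13 from 44826206 to 45016346, was passed over in naming. It was listed at 0 in all 4 control low libraries and held 412 to 2661 fragments in each of the other 8, which a failed estimate would also give. Regions and switched loci were defined after the data had been seen.

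The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter on the 4 groups, robust dispersions and no covariate. All 12 samples entered 1 fit of 4 groups, which share the estimate of spread because the high groups hold only 2 samples each. The filter kept 13749 loci, and p-values were adjusted by the Benjamini-Hochberg method with a two-sided threshold of 0.05. CPM values use the TMM factors. The direction of the low-cell mutant effect was tested in high cells, and the reverse, with fry of limma 3.58.1, and its p-values were adjusted over 4 tests, these 2 and the same 2 for high against low cells between genotypes. Other settings chosen before the data were examined were DESeq2 1.42.0, limma-voom, another normalization, 2 other filters, leaving out each sample, replicate blocks, a fold threshold, leaving out chromosomes X and Y, and fits of only the groups compared. Leaving out both chromosomes replaced a setting on named sex-linked genes. Settings added later are given with their effect.

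Regions were runs of at least 4 loci, merged over both strands, that changed the same way by a log2 fold change of at least 1 with gaps of up to 100 kb. Loci in such runs were counted and compared with 1000 permutations of the calls within 10 expression classes, one-sided. A group with no fragment in any library was given a floor of 3 fragments over the group, and intervals on fragment ratios are exact binomial intervals at 95%. Floors and intervals cover counting error only.

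Library totals ran from 4549011 to 12365078 fragments. The fit was tested on simulated counts for 13184 loci with 200 changed. In the design of the low comparison it recovered 100% of the 4-fold and 30% of the 2-fold changes, with 6 false calls. In the design of the high comparison it recovered 67% and 9%, with 4 false calls. Without any change it made 0 calls in both. The simulated means were set per group, without the shared differences between low libraries described below, so these rates may not carry over to the data. A permutation of regions was tested on 12553 loci with 200 permutations, where calls placed at random gave p = 1. Planted runs gave p = 0.00498, the smallest that 200 permutations give. The regions found, 8 with 39 loci, were fewer than the runs planted. With 1 random set, the rate of false results was not measured. No 2 libraries of a group were alike within sampling noise. The index of dispersion of their fragments, 1 for sampling noise alone, was 22.9 to 80.0 over the 14 pairs within groups.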

Results

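Expression was measured by RNA sequencing in Six2-expressing cells of newborn mouse kidney, a population that includes the progenitors of the nephron. The cells came from control and mutant kidneys and were sorted into populations titled low and high expression. Control low and mutant low cells had 4 samples each, and control high and mutant high cells had 2 each. Total fragments per library ran from 6784907 to 12365078 in control low, from 5948488 to 12317879 in mutant low and from 7779040 to 9307989 in mutant high cells. The control high libraries were the smallest as a group, with 6249263 and 4549011 fragments. The 2 control high libraries held 4.51% and 10.3% of their fragments on chromosome M, against 0.494% to 1.96% in the other 10. Their 100 most abundant loci took 29.1% and 34.4% of fragments, compared with 18.8% to 22.1% elsewhere. Chromosome Y carried 934 to 2101 fragments in 6 libraries (2 of 4 control low, 3 of 4 mutant low, 0 of 2 control high and 1 of 2 mutant high) and at most 2 in each of the other 6. The first principal component, with 63.0% of the variance, separated high from low cells, and the second, with 13.4%, separated control from mutant cells.

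**Figure D1:**
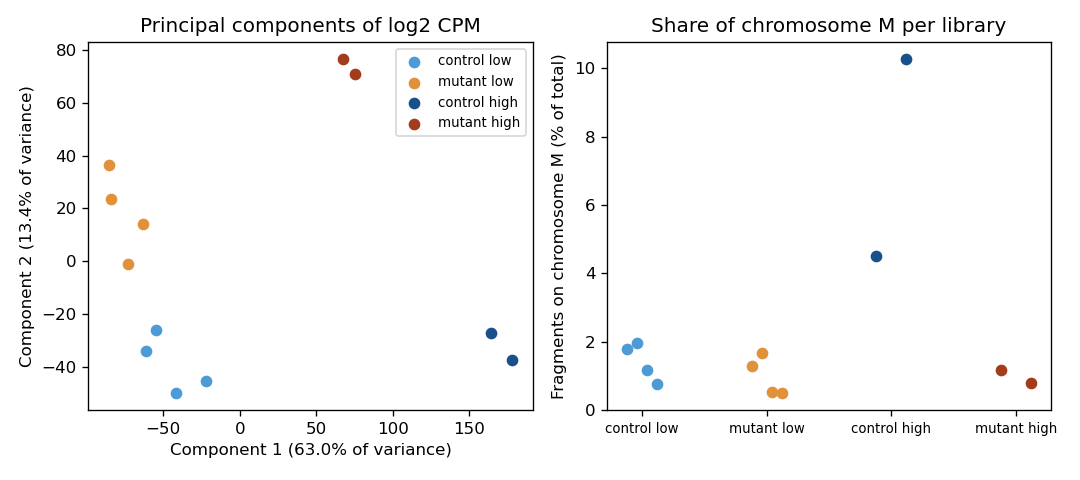
Left, the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; each point is a library and colours mark the 4 groups. Right, the percentage of each library's fragments on chromosome M; the 2 control high libraries stand at 4.51% and 10.3%, above the other 10.

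The first comparison asked which loci differ between mutant and control cells of the low population. Of 13749 loci tested, 663 were higher and 441 were lower in mutant low cells. A group of 116 loci was switched on, with a mean under 0.5 CPM in control low cells, at least 1 CPM in mutant low cells and a rise of at least 2 on the log2 scale. The mirrored group, switched off, held 76 loci. The switched-on loci reached a median of 2.44 CPM in mutant low cells. One of them, on chromosome 13 from 44826206 to 45016346, was listed at 0 in all 4 control low libraries, which a failed estimate would also give, and was left out of the ranking of loci.

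Without that locus, the largest rise among loci that met the naming rule was at uc007npf.2 (chromosome 12, 57632923 to 57637895, minus strand), from 0.0632 ± 0.0734 CPM in control low to 50.2 ± 18.0 CPM in mutant low cells (SD, n = 4 each). Its fold rested on 2 fragments in the control low libraries, and the ratio was 957 with a counting interval of 265 to 7909. The adjusted p in edgeR's quasi-likelihood test was 1.23e-06. At uc008kdu.1 (chromosome 2, 74506366 to 74509655, plus strand), the level rose from 0.178 ± 0.183 to 55.4 ± 22.8 CPM, a log2 fold change of 8.11 (SE 0.51, edgeR adjusted p = 7.76e-07). In mutant high cells these loci stood at 17.0 ± 9.96 and 23.2 ± 3.19 CPM (SD, n = 2), and neither had a fragment in control high cells. Against the floor of 3 fragments over that group they were at least 47.3-fold and 64.5-fold higher. All 8 loci named for the largest rises were also called higher in mutant high cells, and 6 of the 8 named for the largest falls were also called lower there. The 8 falling loci were all called higher in control high than in control low cells, by log2 fold changes of 5.46 to 6.17. They are among the 250 falling loci of this kind described below.

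Among loci that met the naming rule, the largest falls were at uc008gme.2 (chromosome 19, 8692485 to 8702789) and uc007xgc.1 (chromosome 15, 89164903 to 89167438), both on the plus strand. The first went from 33.4 ± 18.5 to 0.996 ± 0.885 CPM (log2 fold change -5.14, SE 0.68, edgeR adjusted p = 0.000600) and the second from 97.6 ± 66.5 to 3.02 ± 1.46 CPM (log2 fold change -5.03, SE 0.63, edgeR adjusted p = 0.000405). The call at uc007xgc.1 was lost with the 8 libraries that share a description number (log2 fold change -4.39, edgeR adjusted p = 0.0624). Both were far more abundant in control high cells, at 1882 ± 695 and 4302 ± 588 CPM (SD, n = 2). This held for many loci that fell. Of the 441, 250 (56.7%) were called higher in control high than in control low cells by at least 2 on the log2 scale, against 14.3% of all loci tested and 19.8% of those that rose. Their level in control low cells was a median 2.79% of that in control high cells. The 191 other loci that fell did not meet that criterion. A region of 4 loci on chromosome 7, 126606379 to 126806029, fell by a median of 3.80 on the log2 scale, with a summed 241 ± 216 CPM in control low and 19.95 ± 17.5 CPM in mutant low cells. With gaps of up to 100 kb, 4 loci that fell lay in regions against 0.403 in permuted calls (permutation p = 0.0959, 0.256 adjusted over 8 tests), and the unadjusted p was 0.029 with gaps of up to 50 kb and 0.017 with gaps of up to 200 kb. Low libraries with description numbers up to 7 differed from those above 7, and the comparison within each gave 726 loci (458 higher, 268 lower) and 855 loci (555 higher, 300 lower). Treating each transcript as a separate feature gave 427, and the 8 libraries that share a description number gave 257 (195 higher, 62 lower). A fit of only the 2 low groups, with 12102 loci tested, gave 650 higher but 282 lower, so the falling count depended more on the high libraries in the fit.

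**Figure D2:**
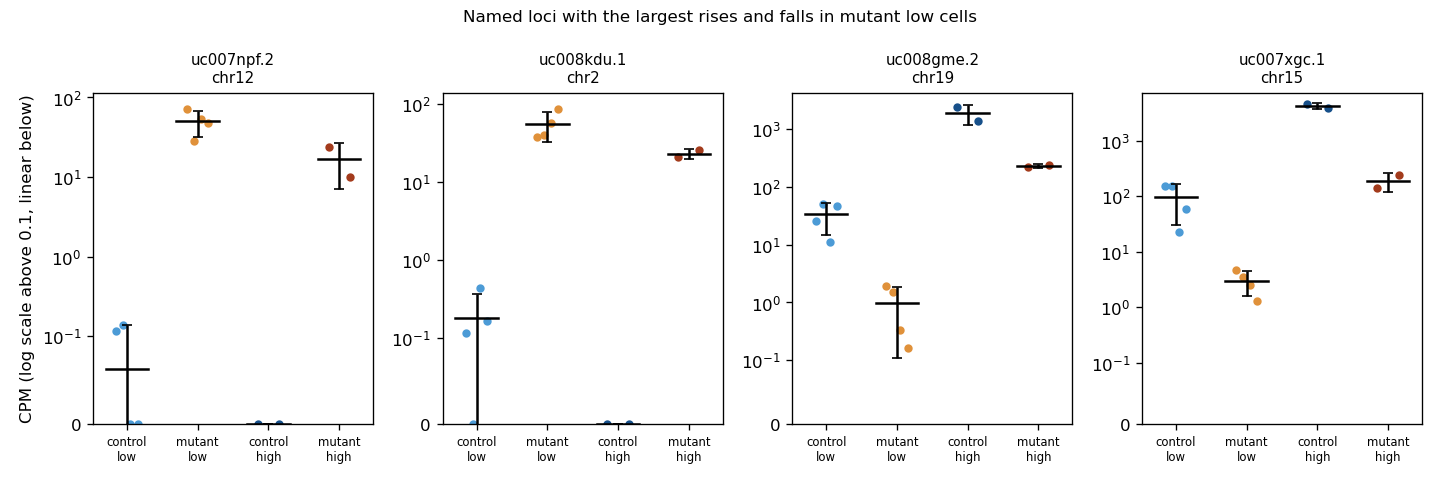
CPM of the 2 loci with the largest rises and the 2 with the largest falls in mutant low cells among those that met the naming rule. Points are libraries, bars are means with SD, and the vertical axis is logarithmic above 0.1 and linear below. Mutant low cells average 50.2 and 55.4 CPM at the loci that rose.

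The same question was asked of the high population. Here 2239 loci were higher and 1541 lower in mutant cells. The group switched on, from under 0.5 CPM in control high to at least 1 CPM in mutant high cells, held 381 loci, and the group switched off held 82. The switched-on loci had a median of 2.64 CPM in mutant high cells. The 8 loci named for the largest rises had no fragment in either control high library and mean levels of 11.6 to 54.4 CPM in mutant high cells. The 8 named for the largest falls went from 10.5 to 818 CPM in control high cells to 0.22 to 7.30 CPM in mutant high cells. These are means of 2 libraries. Relative to the mean, those of the second largest fall were the widest apart, at 0.416 and 33.7 CPM in control high cells. In low cells, 4 of the 8 rises and 2 of the 8 falls were called in the same direction. The switched-on count was 221 without control high replicate 1 and 216 without control high replicate 2. The switched-off count was 25 without control high replicate 2, 39 without mutant high replicate 1 and 24 without mutant high replicate 2.

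In a region on chromosome 15, 102751561 to 102847860, 6 of 7 loci tested rose in mutant high cells, and their summed level was 44.9 ± 0.736 CPM in control high and 130 ± 24.3 CPM in mutant high cells (SD, n = 2). In low cells the same loci summed to 523 ± 107 CPM in control and 436 ± 113 CPM in mutant samples (SD, n = 4). The sum hides a rise at the locus from 102751561 to 102759245. That locus went from 0.169 ± 0.256 CPM in control low to 27.9 ± 4.72 CPM in mutant low cells (edgeR adjusted p = 6.99e-06). In high cells it had no fragment in control and 19.1 ± 5.25 CPM in mutant samples. Low-cell changes at the other loci are not given here. Across the genome, loci that rose showed no excess in such regions, with 61 against 125 on average in permuted calls (permutation p = 0.999, one-sided for an excess) and 37 against 42.3 with gaps of up to 50 kb (p = 0.664). Loci that fell lay in them more often than permuted calls, 103 against 42.4 (p = 0.001, the smallest that 1000 permutations give, 0.008 adjusted over 8 tests). The permutations held expression class, but not locus span or the density of loci, and were not repeated with the span trend removed. The excess may therefore reflect where loci of such spans or surroundings lie. A region on chromosome 14, 56194510 to 56377261, held 7 of the loci that fell, at 2662 ± 544 CPM in control high and 412 ± 32.5 CPM in mutant high cells. Another on chromosome 17, 25931515 to 26227109, also held 7, at 1369 ± 64.7 and 471 ± 41.8 CPM. On chromosome M, 7 of 8 loci were lower in mutant high cells, with a median log2 fold change of -3.34. With 2 samples a group, single libraries mattered, and the count was 2450 without control high replicate 1, 1996 without control high replicate 2 and 2164 (1563 higher, 601 lower) without mutant high replicate 2. With the trend on locus span removed, 1839 loci were higher and 1857 lower. With each transcript as a feature it was 2012.

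The mutant effects in the 2 populations share no library, but the labels do not say whether high and low samples came from the same animals. Loci higher in both numbered 419, where independent lists of these sizes would share 108, and loci lower in both numbered 212, where 49.4 would be shared. Opposite calls were rarer. There were 16 loci higher in low and lower in high cells, with 74.3 for independent lists, and 44 of the reverse, with 71.8. Of the 1104 loci called in low cells, 83.1% had a log2 fold change of the same sign in high cells (adjusted p = 1.77e-06 over 4 tests with fry of limma). Called there in the same direction were 631, and in the opposite direction 60. The share with the same sign was 98.4% for the 250 falling loci that were higher in control high cells by at least 2 on the log2 scale. It was 78.6% for the other 854. Of the 3780 called in high cells, 74.4% had the same sign in low cells (adjusted p = 0.000443 with fry of limma), where 631 were called in the same direction and 60 in the opposite. Loci switched on in both populations numbered 57. Of the 116 loci switched on in low cells, 75 were called higher and 1 was called lower in mutant high cells. Across loci, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.49.

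The size of the mutant effect differed between the populations at 1422 loci by the interaction test, more positive in high cells at 1002 and more negative at 420. The 4 loci named above were not among them. Of the 8 loci on chromosome M, 4 had a more negative effect in high cells. DESeq2 put 1055 loci on the positive side and 720 on the negative, and with the trend on locus span removed the split was 738 and 623. The count was 835 without control high replicate 1, 572 without control high replicate 2, 663 without mutant high replicate 2 and 544 with each transcript as a feature.

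**Figure D3:**
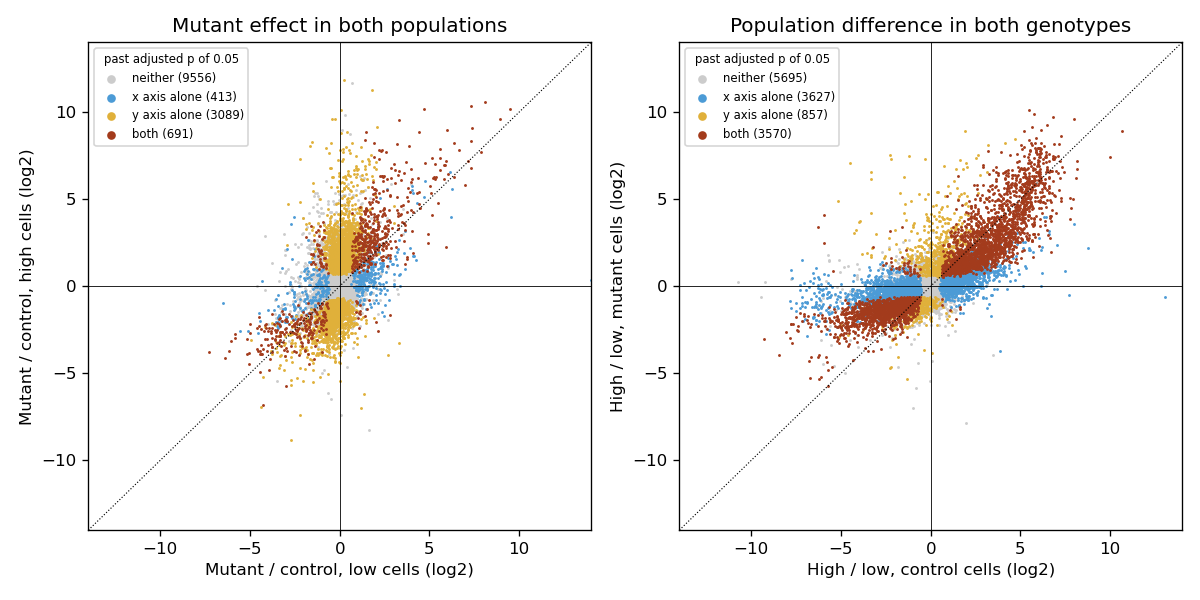
Log2 fold changes of 13749 loci. Left, mutant over control in low cells (horizontal) and high cells (vertical); 691 loci passed an adjusted p of 0.05 in both. Right, high over low in control cells (horizontal) and mutant cells (vertical); 3570 passed in both. Each point is a locus and the dotted line marks equal change.

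High and low cells of control kidneys differed at 7197 loci, 52.4% of those tested. Of these, 3478 were higher and 3719 lower in high cells. With RLE in place of TMM they were 3692 and 3387, and with DESeq2 3746 and 3531, so the direction with more loci depended on the scaling or tool. In the edgeR test with TMM, 734 rose and 348 fell by at least 4 on the log2 scale. The 8 loci named for the largest rises had at most 2.49 CPM in control low and 15.2 to 3970 CPM in control high cells, and all 8 were also called higher in mutant high than mutant low cells. The 8 with the largest falls had 8.75 to 27.7 CPM in control low and at most 0.312 CPM in control high cells. A region on chromosome 7, 148264127 to 148646642, held 12 loci that were higher, summing to 209 ± 32.1 CPM in control low (n = 4) and 1110 ± 167 CPM in control high cells (SD, n = 2). On chromosome 10, 80261479 to 80788996, 10 loci fell together from 2088 ± 279 to 695 ± 130 CPM. Neither direction lay in regions more often than permuted calls after adjustment over the 8 tests (adjusted p = 0.364 for higher and 0.104 for lower loci). On chromosome M, 7 of 8 loci were higher in control high cells, with a median log2 fold change of 2.91.

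In mutant kidneys high and low cells differed at 4427 loci, 2613 higher and 1814 lower in high cells. Loci higher in high cells of both genotypes numbered 2024, where independent lists would share 661, and those lower in both numbered 1497, where 491 would be shared. Only 49 loci were called in opposite directions. On chromosome 13, 23931302 to 24569154, all 6 loci tested were higher in mutant high cells, summing to 70.9 ± 11.9 CPM (n = 2) against 3.48 ± 0.491 CPM in mutant low cells (SD, n = 4). They summed to 360 ± 144 CPM in control high and 13.01 ± 3.56 CPM in control low cells. On chromosome 15, 102797295 to 102867283, 5 loci were lower, at 111 ± 19.4 CPM in mutant high and 407 ± 110 CPM in mutant low cells. This stretch overlaps the chromosome 15 region described above, whose summed level was also lower in control high than in control low cells. Neither direction lay in regions more often than permuted calls. Higher loci in regions numbered 186 against 167 (permutation p = 0.364 adjusted over 8 tests) and lower loci 25 against 29.8 (0.904). The median log2 fold change of the 8 loci on chromosome M was 0.25.

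The difference between the populations tended to be smaller in mutant cells at loci lower in high cells, while at loci higher in high cells this depended on how they were chosen. Among the 3719 loci lower in control high cells, the median log2 fold change was -1.68 in control and -0.76 in mutant cells, and the interaction test called 851 of them smaller and 0 larger in mutant cells. Among the 3478 higher ones the medians were 2.24 and 1.31, with 402 called smaller and 34 larger. Choosing loci by the control difference favours large values there. Among the 1814 loci chosen because they were lower in mutant high cells, the control difference was still larger, with medians of -1.27 in mutant and -1.73 in control cells, and the interaction test called 301 smaller and 21 larger in mutant cells. Among the 2613 chosen because they were higher, the medians were 2.23 and 2.46, the median ratio of control to mutant change was 1.02, and 170 were called smaller and 187 larger in mutant cells. The count in mutant cells was 2883 without mutant high replicate 1 and 2713 with each transcript as a feature. With the trend on locus span removed it was 2220 higher and 3018 lower.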

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

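The tests of the description numbers, of chromosome Y, of carried-over cells or shared libraries and of other splits were chosen after the results had been seen. The mutant effect differed between high and low cells at 1422 loci by the interaction test, which is what drew attention to it. The control high libraries had the lowest mean total of the 4 groups, although 1 mutant low library was smaller than 1 of them, and the most chromosome M and the most fragments in few loci. Thinning every library to the smallest total gave 1276 loci, 1131 of them among the 1422 with the same direction. Dropping chromosome M and the 100 most abundant loci of each control high library gave 1374 (1344 shared), and removing each library's trend on locus span gave 1361 (1147 shared). The thinned and span-adjusted counts argue against total depth or span as the whole cause, although span removal moved the split from 1002 and 420 to 738 and 623. Thinning equalized totals, but not the fragments left to other loci in the control high libraries. Dropping abundant loci does not return the fragments they took, and TMM already scales for them, so that count cannot decide on them. RNA quality was not measured here, and a different response of the sorted populations stays open as a hypothesis, with only 2 control high samples behind it (572 loci without replicate 2, 835 without replicate 1).

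Low libraries deviated from their group means together across genotypes. The 8 pairs of a control and a mutant library on the same side of description number 7 had correlations across loci of 0.0671 to 0.467, and the 8 pairs on different sides -0.419 to -0.0749, a gap of 0.142. Deviations are taken from group means, so positive values on the same side force negative ones across sides, and only the same-side values bear on the pattern. A batch that follows these numbers may be the source, but no label states one. The presence of chromosome Y alone does not account for the pattern, because same-side pairs that differ in it still correlated at 0.0671 to 0.284. Same-side pairs alike in it correlated more, at 0.287 to 0.467, so a part of chromosome Y or sex in these deviations stays open. The test on same-side pairs replaced a first one on means (0.0719 for pairs alike in chromosome Y, -0.0715 for pairs unlike), which had decided nothing. No other biological explanation was tested. With a term for the numbers the mutant effect in low cells covered 1344 loci. In high cells the numbers are not balanced, as both mutant libraries have numbers up to 7 and the control libraries lie on different sides. A batch that follows them would be partly confounded with the mutant effect in high cells, and with its difference from that in low cells.

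Of the 35 splits of the 8 low libraries into 4 and 4, only the real one (1 of 35) gave as many as 1104 loci. The 35 are not interchangeable, because the low libraries differ by description number, so this share does not exclude chance. The 18 splits with 2 libraries from each side of number 7 in both arms are too few for a share under 5%, and the highest other among them gave 1 locus. The highest other split gave 816 loci and is the one that parts the description numbers, a structure of the samples rather than of the genotype. The remaining splits gave at most 2. Within the numbers up to 7 and above 7 the mutant comparison gave 726 and 855 loci.

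Loci that fell in mutant low cells were often loci of control high cells. Control low libraries enter both comparisons on the same side. Sharing them would make falling loci look lower in control high cells, not higher, so it could not give this pattern. Splitting these libraries between the comparisons was therefore no test of it. With the split, at least 76% of the falling loci were higher in control high cells. High cells carried into the control low sort could give such a fall, as 250 of the 441 loci stood at a median 2.79% of their control high level. Of 554 loci with at least 100 CPM in control high cells and a log2 rise of at least 2 there, 36 (6.50%) were under 1.40%, 50% of that share. This set was narrowed after a first run on all 2239 loci with at least 100 CPM in control high cells had given 37 (1.65%). The wider set adds loci that low cells may express themselves, which would mask a carried share. Among the 554, the share was 0.0628% at the lowest locus and 1.24% at the 5th percentile. A uniform share of 2.79% was therefore not reached at the 36 loci. The bound of 5%, itself a choice, lies between the 2 values, so the test does not decide on one uniform share. The 250 loci fell by a median of 2.28 on the log2 scale in mutant high and 2.55 in mutant low cells, and stood in mutant low cells at a median 1.70% of their mutant high level, so carry-over in both genotypes could also give part of the agreement between the mutant effects of the 2 populations. Without them, 78.6% of the other 854 loci called in low cells had a log2 fold change of the same sign in high cells, whether called there or not. Carry-over of all or a part of the high cells, and a change within low cells, cannot be told apart, because sort purity was not measured here.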

How the results depend on the processing

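Alternatives on description numbers without a block, features, strands, chromosome M, depth, abundant loci, span and region gaps were chosen after seeing the data. Directions of the 4 named loci held in every fit that tested them, and 1 call was lost, uc007xgc.1 with the 8 libraries that share a description number (log2 fold change -4.39, adjusted p = 0.0624, against a range of 5.33e-20 to 0.0624 over its 27 alternatives). All 30 alternatives for control high against low stayed within 1.5 times of the main count. Each transcript as a feature divides fragments between isoforms and gave 427 loci for mutant low, 2012 for mutant high, 2713 for high against low in mutant cells and 544 for the difference of mutant effects. Numbers up to 7 alone, with 2 samples a group, gave 726 for mutant low. Leaving out 1 sample gave 774 to 1149 for mutant low, 1996 to 4010 for mutant high, 5158 to 7398 for high against low in control cells, 2883 to 4460 in mutant cells and 572 to 1482 for the difference of effects, and 68 to 74 of 74 named loci stayed past the threshold. Where an arm was left with 1 sample, it was assumed to vary like the other groups.

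Titles and descriptions share numbers between groups. Deviations of same-numbered low samples by title correlated at 0.0671 to 0.467, and of high and low samples by description at 0.225 and 0.136 in mutant but -0.0555 and -0.0836 in control cells, and the samples were tested as unpaired. The replicate block by title number gave 1331, 4454, 7023, 4042 and 1921 loci for the 5 counts in the same order. The replicate block by description number gave 6477, 3459 and 942 for the last 3, and the same 8 libraries without the block gave 6535, 3329 and 865, with 257 for mutant low. The cause of the 257 was not tested.

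With RLE in place of TMM the median log2 fold change of all loci in control high against low moved from -0.13 to -0.03, and with the span trend removed that of mutant high against low moved from -0.03 to -0.29. Switched-on loci in mutant low cells numbered 22 to 122 over the alternatives and in mutant high cells 95 to 396, lowest with the filter of 5 CPM, which removes loci of low level. Switched-off loci in mutant low cells numbered 11 to 89, with 11 for the 8 libraries that share a description number, 25 with only the 2 groups compared, and 48 and 36 with numbers up to 7 and above 7. Switched-off loci in mutant high cells fell to 0 with the filter of 5 CPM and to 35 with thinned libraries. Regions of falling loci in mutant low cells gave permutation p = 0.029 and 0.017 with gaps of 50 and 200 kb, against 0.0959 at 100 kb, and those of lower loci in control high cells 0.0829 and 0.135 against 0.026, all unadjusted. The alternatives for the fixed gene lists and for named sex-linked genes were not run, since the file gives no gene names. Thinning to the smallest total gave 947, 3516, 6782, 4072 and 1276 loci for the 5 counts. Simulated counts with 200 changed loci, in the design of the high comparison with 2 samples a group, gave back 9% of 2-fold changes.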

Other observations

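With the control low libraries split between the comparisons in 4 ways, 358, 330, 372 and 378 loci rose in mutant low cells. Of these, 122, 82, 112 and 109 were called higher in control high than in control low cells, where independent lists would give 79.7, 71.3, 83.1 and 85.3. Called lower there were 65, 71, 82 and 89, where independent lists would give 77.1, 73.7, 82.2 and 87.0. Of 445 loci tested on chromosome X, 27 were higher and 13 lower in mutant low cells, and 92 were higher and 36 lower in mutant high cells. The groups compared differ in sex chromosomes, with chromosome Y fragments in 2 of 4 control low, 3 of 4 mutant low, 0 of 2 control high and 1 of 2 mutant high libraries. The presence of chromosome Y agreed in 4 of 4 pairs of a high and a low sample that share a description number, against 8 of all 16 pairs of a high and a low sample of one genotype, as it would if a number marked 1 animal. High and low samples are therefore not known to be independent. This comparison was chosen after the values had been seen.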
